A study of Bos taurus with 28 samples.

How the data were processed

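Liver RNA of 14 Holstein cows was measured on 28 cDNA microarrays, 2 arrays per cow with the dyes exchanged, each against a common reference made from several cattle tissues. The labels put 7 cows in a healthy group and 7 in a ketosis group. Cows are named by group and by a replicate number that only names a cow and pairs none across the groups. Both arrays of a cow came from the same liver RNA and were counted as 1 replicate, so n is 7 cows per group.

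The deposited values are log2 ratios of the 2 dye channels, 1 per spot, and the arrays' own processing is not given in the sources used here. The values were not centred: the array medians of the deposited log2 ratios ran from -1.05 to 2.16. A ceiling of 16.61, the log2 of a ratio of 100000, held 6245 values and was read as no measured ratio, as were 103458 empty cells. Another 5777 values were exactly 0 and were kept. Scanner intensities were not used here, so no filter on dim spots and no intensity-dependent normalisation could be applied.

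The ratios' direction was taken from the dyes in the titles and from marker genes; the label fields of 1 ketotic array name the same dye for both channels. Arrays with liver in Cy3 were sign-turned. After turning, the hepatocyte markers lay above the genes of tissues other than liver on 28 of 28 arrays, by a median of 5.82 on the log2 scale (lowest 2.57). The direction is therefore called likely: liver over reference, with Cy5 as the numerator. In the deposited form, arrays with the same liver dye correlated across probes at a median r of 0.732 and arrays with opposite dyes at -0.617.

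Each array was centred on its median. This departs from the design fixed before the data were examined, which took the values as deposited in the belief that they were already normalised. The change was made from the array medians alone, before the groups were compared, and the fit on the values as deposited stands among the alternatives. Adjacent spots, which correlated within arrays while other neighbours did not, were averaged to 13824 probes from 27648 spots. The design text gives a smaller number of elements per array; the gap was not resolved, and control spots, which could not be told apart, may be among the probes. A cow's value needed both arrays, and a probe needed values in at least 5 cows of each group, which left 10420 probes.

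Gene names came from the platform annotation supplied with the data, updated through gene IDs with the table of assembly ARS-UCD2.0, which held 8620 of the probes with a single symbol. Of the probes, 8645 had 1 gene symbol, 105 had several and 5074 had none; none was named from several symbols. The annotation can be old, and no coordinates are given because the array's build is not named. A gene's value was the mean over its probes, each probe centred first, which gave 6958 tested genes, 365 of them with more than 1 probe. No gene had passing probes in opposite directions.

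Groups were compared with limma (version 3.58.1, in R 4.3.3) by lmFit and eBayes on the 14 cows, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors. Before the data were examined, 36 gene lists were fixed: 26 pathways and complexes and 10 sets of cell type markers. The 33 lists with at least 5 measured genes were tested with a camera-type statistic at a preset correlation of 0.01, and with the correlation estimated from the data. After seeing those results, an exact permutation test was added on each cow's median over the list, with genes first centred over cows, two-sided over the 3432 ways to choose 7 of 14 cows, and adjusted over the 33 lists. Its smallest possible p is 0.000583.

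The genes named were set by a rule fixed in advance: the 6 largest rises and 6 largest falls among passing genes, up to 2 passing members of each list by smallest p (or the member with the smallest p where none passed), and 26 fixed genes of lipid and glucose metabolism, of which some of the list members are left out of the text. Some of the fixed genes had no named probe, among them FGF21, G6PC, GHR, INSIG1, SCD, SAA3, HP and CYP7A1.

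The fit was tested on simulated data for this comparison, 20 times over 6958 genes, with the real means, spreads, cow-specific noise and missing values. Of 200 genes changed per run, 20.7% were recovered at a log2 change of 0.5, 73.0% at 1 and 95.0% at 2, with 4.41% of calls false. A list shifted by -1 passed in 20 of 20 runs with either correlation; the simulated genes were independent, so the correlation between genes was not tested there. Figures were drawn with matplotlib 3.10.9.

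Alternatives covered the scaling, the dyes, the filter, the model, the weights, the threshold, each cow left out in turn, and choices made after seeing the data; their effects are given at the end. The number of arrays limits the precision. The labels give no hybridisation batch, so none was tested.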

Results

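Liver gene expression was compared between cows with ketosis brought on by feed restriction and healthy cows early after calving. Ketosis is the rise of ketone bodies when a cow draws on body fat faster than the liver can burn it. Cows were examined on day 4 after calving and assigned to the groups at random. From day 5, cows of the ketosis group received 50% of their earlier intake until clinical signs or day 14 at the latest; this is the design text, while the sample labels start the restriction on day 4. The question was which liver genes differ between the states. There were 7 cows per group and 2 dye-swapped arrays per cow.

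The 2 arrays of a cow correlated across probes at a median r of 0.673, and different cows at a median of 0.847 once their arrays were averaged. These values are not like for like. Single arrays of different cows with the same liver dye correlated at a median of 0.732, above that of a cow's own pair. Arrays with opposite dyes, own pairs included, correlated at -0.617 before turning. Healthy cow 7 stood apart: it correlated at 0.363 to 0.462 with the other cows, which correlated with each other at 0.716 or more. Its values are kept, and the main counts are also given without it. The share of spots without a usable ratio was 16.5% ± 4.49 (SD, n = 7) in ketotic and 11.9% ± 2.80 (SD, n = 7) in healthy cows (exact permutation p = 0.0338, adjusted over 4 measures 0.0676). The spread of the log2 ratios, as median absolute deviation, was 1.27 ± 0.192 against 0.992 ± 0.125 (exact permutation p = 0.00932, adjusted 0.0373).

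**Figure D1:**
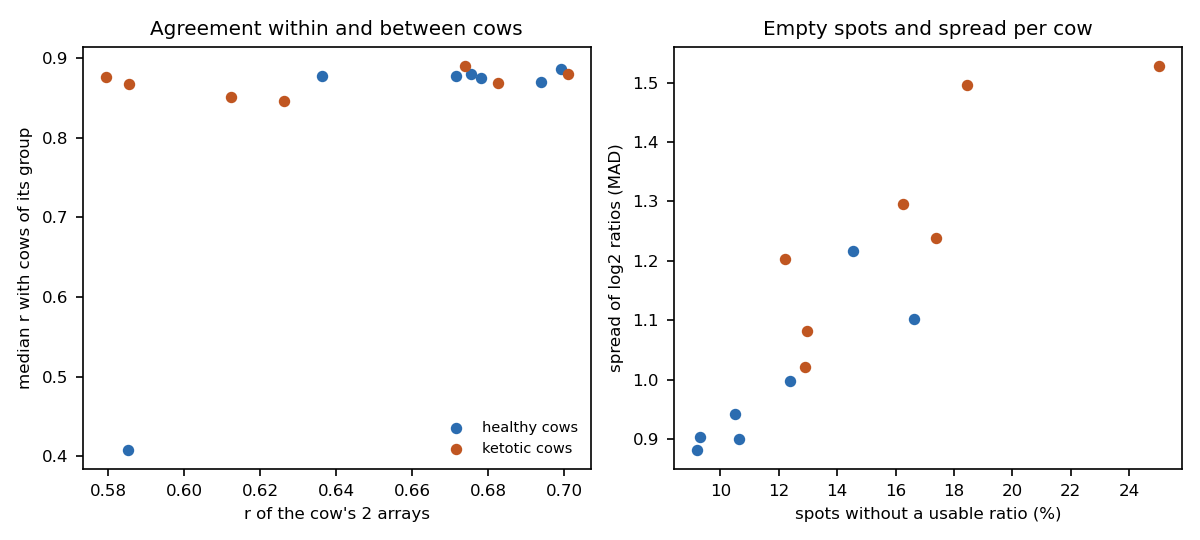
Left, the correlation (r, across probes) of each cow's 2 arrays against its median correlation with the other cows of its group; right, the percent of spots without a usable ratio against the spread of the log2 ratios, with 1 point per cow. Healthy cow 7 lies alone on the left at a median r of 0.408, and ketotic cows lie on average higher on both axes on the right.

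The largest falls in ketotic liver were those of FADS2 and FADS1, and most genes that passed were lower. FADS2, the delta-6 desaturase of polyunsaturated fatty acids, fell by 4.10 on the log2 scale (SE 0.974, 17.1-fold lower, limma adjusted p = 0.0147, n = 7 per group), with 6 of 7 ketotic cows below the healthy mean. FADS1, the delta-5 desaturase, fell by 2.75 (SE 0.545, 6.74-fold, adjusted p = 0.00776) with values in 5 ketotic cows. AIF1L fell 5.84-fold (adjusted p = 0.00112), ACSS2, which makes acetyl-CoA from acetate, 3.61-fold (adjusted p = 0.0240), LSS, the lanosterol synthase, 3.50-fold (adjusted p = 0.00243) and PLAC8A 3.28-fold (adjusted p = 0.00549).

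The largest rises were CD101 (3.50-fold, adjusted p = 0.0246), MYOD1 (3.48-fold, 0.00932), FRZB (3.29-fold, 0.0477), ETFRF1 (3.24-fold, 0.0228), FBP1 (1.68 on the log2 scale, 0.0147) and IVL (1.68 on the log2 scale, 0.0113). Only FBP1, the fructose-bisphosphatase of gluconeogenesis, had a probe with a value at every spot of all arrays among these 6; it was higher than the healthy mean in 7 of 7 ketotic cows. The other 5 had values in 5 or 6 cows of each group. FRZB had a difference of -0.18 when ratios at the ceiling were kept, and CD101 one of 0.11. Without healthy cow 7 FRZB had an adjusted p = 0.0652, and CD101 and ETFRF1 had too few values to be tested.

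Over all 6958 genes, 929 passed, 64 higher and 865 lower in ketotic cows; 24 rose and 182 fell by at least 2-fold. Among 10420 probes, 1050 passed, 106 higher and 944 lower. The median difference over all genes was -0.18. The probe count was 1649 without healthy cow 7 (182 higher, 1467 lower), with 1368 genes (103 higher, 1265 lower), and 906 of 923 passing genes tested in both passed again in the same direction. Scaling set the size and split: with every array centred on the same 5533 probes, 198 probes were higher and 591 lower, and 119 genes were higher and 551 lower, while values as deposited gave 21 probes higher and 2838 lower. With the liver in Cy3 alone 690 genes passed and with the liver in Cy5 alone 12, and with the share of empty spots as a covariate 168 did.

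Several lists of energy metabolism had lower per-cow medians. Of 76 measured oxidative phosphorylation genes, the subunits of the respiratory chain and ATP synthase, 31 fell and none rose; 48 fell adjusted over the list alone, and 51 fell without healthy cow 7. NDUFB5 of complex I fell 2.42-fold (adjusted p = 0.00241) and ATP5MC3 of ATP synthase 1.99-fold (adjusted p = 0.00186). The list's median difference was -0.56, and its per-cow median was lower in 7 of 7 ketotic cows than the healthy mean (exact permutation p = 0.00117, adjusted 0.00641). Of 18 tricarboxylic acid cycle genes 4 fell (10 without healthy cow 7), 8 adjusted over the list alone, among them SDHC (2.07-fold, adjusted p = 0.00989) and MDH2 (1.65-fold, 0.0106), with the same exact permutation p of 0.00117. Of 23 genes of glycolysis and the pentose phosphate pathway 7 fell, 9 adjusted over the list alone. GPI fell 2.15-fold (adjusted p = 0.00336) and PGAM1 2.10-fold (adjusted p = 0.00308), and the list's exact permutation p was 0.000583, the smallest possible. With an estimated correlation, adjusted p = 0.63 for each of these 3 lists in the camera-type test.

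Lists of protein synthesis and breakdown had lower per-cow medians too. Of 39 proteasome genes 21 fell (26 without healthy cow 7), 29 adjusted over the list alone, with a median of -0.61; PSME1 fell 2.25-fold (adjusted p = 0.00241) and PSMB4 2.28-fold (adjusted p = 0.00250). Of 56 cytosolic ribosomal protein genes 30 fell (40 without healthy cow 7), 35 adjusted over the list alone, with a median of -0.60; FAU fell 2.11-fold (adjusted p = 0.00336) and RPLP1 1.94-fold (adjusted p = 0.00312). Both lists had an exact permutation p of 0.000583 (adjusted 0.00641), and adjusted p = 0.63 with an estimated correlation. Of 71 ubiquitin conjugation genes 10 fell (14 without healthy cow 7), among them UBE2E1 (1.80-fold, adjusted p = 0.00331) and CUL4A (1.43-fold, 0.0237), and the list's adjusted exact permutation p was 0.0192. Its adjusted p was 0.846 with an estimated correlation, and its median was -0.14, against -0.18 over all genes.

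**Figure D2:**
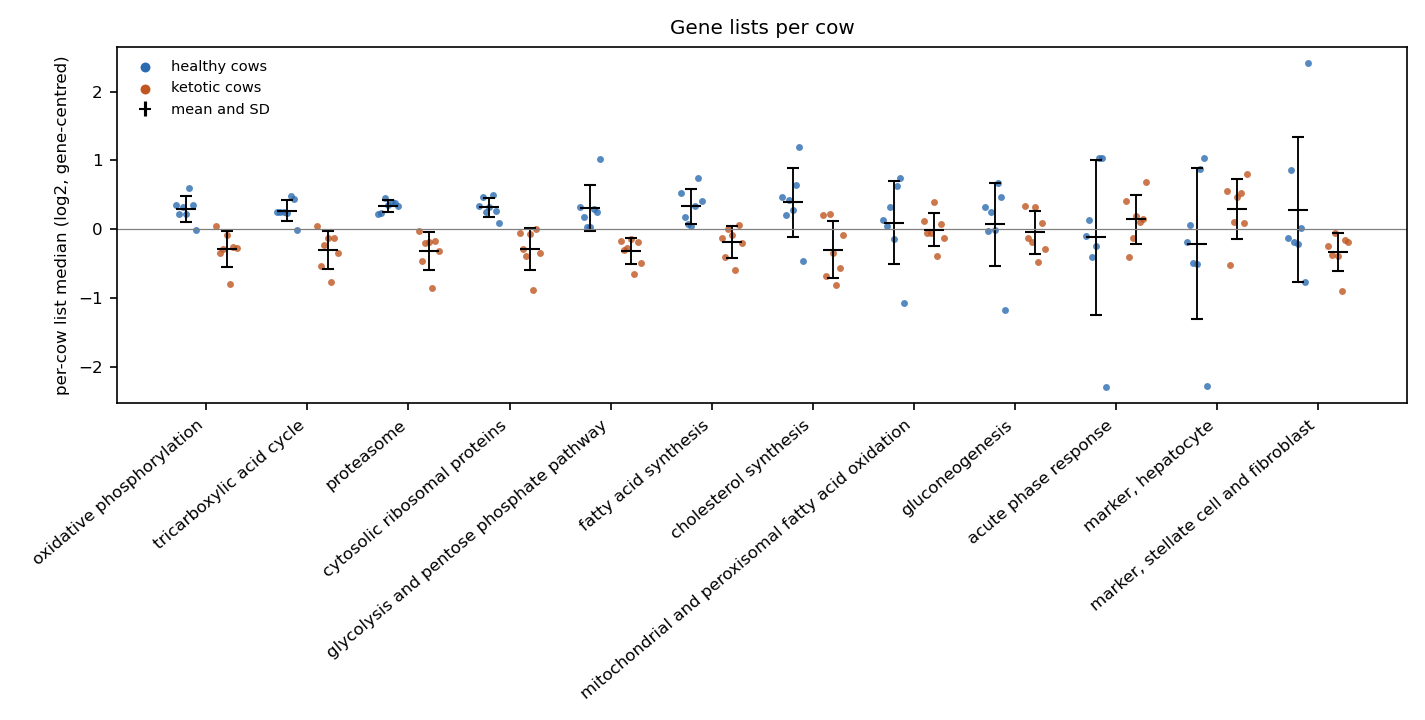
Median over the members of 12 gene lists in each cow, on the log2 scale with every gene centred over cows; points are cows, bars the mean and SD of 7 cows per group. Ketotic cows averaged -0.29 and healthy cows 0.29 for oxidative phosphorylation, whereas the acute phase and hepatocyte lists overlapped and held healthy cow 7 as the lowest point.

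Some genes of lipid synthesis fell, and most did not pass. Of 15 fatty acid synthesis genes 4 fell (6 without healthy cow 7), 7 adjusted over the list alone; the list's exact permutation p was 0.00117 (adjusted 0.00641), but its adjusted p = 0.63 with an estimated correlation. FASN, the fatty acid synthase, fell 1.80-fold (adjusted p = 0.0420), and ACACA, which makes malonyl-CoA, had a difference of -0.78 (adjusted p = 0.0564; 0.0446 without healthy cow 7). Of 13 cholesterol synthesis genes 4 fell, 5 adjusted over the list alone, and 8 without healthy cow 7; SQLE, the squalene epoxidase, fell 2.47-fold (adjusted p = 0.0300) and the list's adjusted exact permutation p was 0.0444, with an adjusted p = 0.63 at an estimated correlation. Of 23 fatty acid oxidation genes 1 fell, ETFA (1.99-fold, adjusted p = 0.0203), and 4 fell without healthy cow 7. CPT1A, which carries fatty acids into mitochondria, had a difference of -0.39 (adjusted p = 0.388; -0.61 and 0.0481 without healthy cow 7) and ACADVL one of 0.077 (adjusted p = 0.913; -0.26 without that cow). Of 12 genes of fatty acid uptake and activation, DBI alone fell (2.67-fold, adjusted p = 0.0185), and 3 genes fell without healthy cow 7.

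Of the 15 genes of the PPARA and fasting list, FADS2 alone passed, and 2 genes fell without healthy cow 7. PDK4 had a difference of 0.39 (adjusted p = 0.434), ANGPTL4 of 1.05 (0.161) and PPARA of 0.22 (0.813); without healthy cow 7 the differences were 0.15, 0.65 and -0.13. None of 3 ketone body genes passed, of which BDH2 had the smallest p (-0.63, adjusted 0.147). Of 16 gluconeogenesis genes FBP1 rose, and ENO1 and MDH2 fell; without healthy cow 7, 2 rose and 3 fell. PCK1 had a difference of 0.60 (adjusted p = 0.294; 0.31 without healthy cow 7), and PC, the pyruvate carboxylase, of 0.79 (adjusted p = 0.0685; 0.0404 without healthy cow 7). None of 15 triacylglycerol and lipid droplet genes passed; PLIN2 had a difference of -0.19 (adjusted p = 0.740; -0.040 without healthy cow 7). SREBF1 had one of -0.16 (adjusted p = 0.587; -0.022 without that cow).

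Single genes of secreted liver proteins rose, but not under every scaling. ALB, which encodes albumin, rose 3.06-fold (adjusted p = 0.0228), APOA4 2.47-fold (adjusted p = 0.0336) and APOA1 1.82-fold (adjusted p = 0.0208), each above the healthy mean in 7 of 7 ketotic cows. With arrays scaled to one spread, ALB had a difference of -0.074 and APOA1 of -0.027. Of 20 hepatocyte markers 2 rose, with a list median of 0.53, of 0.14 without healthy cow 7, and of -0.67 with one spread; the list's exact permutation p was 0.298. Of 17 lipoprotein genes 2 rose and 2 fell; without healthy cow 7, 3 rose and 5 fell. APOB had a difference of -0.26 (adjusted p = 0.920; 0.0412 without healthy cow 7, at -1.44), and MTTP of -0.015 (adjusted p = 0.990; -0.66 without that cow). Of 21 acute phase genes ALB alone rose, and none of 23 complement and coagulation genes passed; without healthy cow 7, 2 acute phase and 3 complement genes fell. The acute phase, complement, lipoprotein, triacylglycerol, hepatocyte and skeletal muscle lists passed the camera-type test upward with the preset correlation, and had an adjusted p = 0.63 with an estimated correlation. With the preset correlation, no list passed upward with one spread, and 1 did with quantile normalisation. None did without the 25% of probes with the largest dye difference. Without healthy cow 7 only the hepatocyte and skeletal muscle lists passed upward with the preset correlation; the adjusted p was 0.329 for acute phase, 0.909 for complement, 0.525 for lipoprotein and 0.295 for triacylglycerol genes.

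In the growth hormone and insulin list of 21 genes IGF2R alone fell (2.36-fold, adjusted p = 0.00194), and 2 genes fell without healthy cow 7. IGF1 had a difference of -0.59 (adjusted p = 0.497; -1.01 and 0.0535 without healthy cow 7) and IGFBP3 of -0.34 (adjusted p = 0.388). Of 29 oxidative stress genes 8 fell (14 without healthy cow 7), 12 adjusted over the list alone with 1 rise, among them GSTA4 (2.65-fold, adjusted p = 0.00921) and PRDX5 (2.01-fold, 0.00302). Of 19 endoplasmic reticulum and amino acid stress genes 3 fell (5 without healthy cow 7), with ATF4 (2.06-fold, adjusted p = 0.00563) and CALR (1.80-fold, 0.0126) among them. Of 23 cytokine and NF-kappaB genes RELA (2.11-fold, adjusted p = 0.00243) and JAK1 (1.85-fold, 0.00341) fell, and 4 genes fell without healthy cow 7. PCNA fell 3.07-fold (adjusted p = 0.00314) and CDK4 1.65-fold (adjusted p = 0.0195) among 27 cell cycle genes, 3 of which fell. ADH5 (2.74-fold, adjusted p = 0.00719) and FMO5 (1.63-fold, 0.0185) fell among 21 cytochrome P450 and conjugation genes, and 3 of 20 without healthy cow 7. No gene passed among 24 of amino acid catabolism, 7 of the urea cycle and 4 of bile acid synthesis. Without healthy cow 7, 7 amino acid catabolism genes fell, QDPR among them (adjusted p = 0.0180, from 0.0606), and in the urea cycle list GLUD1 fell (adjusted p = 0.00488, from 0.0979).

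Markers of other cell types were also measured. Of 11 macrophage markers 4 fell, among them LAPTM5 (1.94-fold, adjusted p = 0.00731) and CD74 (1.84-fold, 0.00597); the list's adjusted exact permutation p was 0.0417, with an adjusted p = 0.63 at an estimated correlation. Of 8 bile duct markers KRT8 fell 1.997-fold (adjusted p = 0.00984), with an adjusted exact permutation p of 0.0214 for the list and 0.769 at an estimated correlation; 3 of 7 fell without healthy cow 7. Of 9 lymphocyte markers CD79B rose 1.80-fold (adjusted p = 0.0275) and GNLY fell 1.61-fold (adjusted p = 0.0339). MMP9, the only passing neutrophil marker of 6, rose 2.38-fold (adjusted p = 0.0477) and had too few values to be tested without healthy cow 7, where another marker fell. No marker passed among 15 of stellate cells and fibroblasts, 9 of endothelial cells, 6 of adipocytes, 9 of skeletal muscle and 4 of blood. The stellate list had a median of -0.77, and -0.37 without healthy cow 7, where DCN fell (adjusted p = 0.0409, from 0.0752); 1 of 4 adipocyte markers and 1 of 20 hepatocyte markers also fell there.

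**Figure D3:**
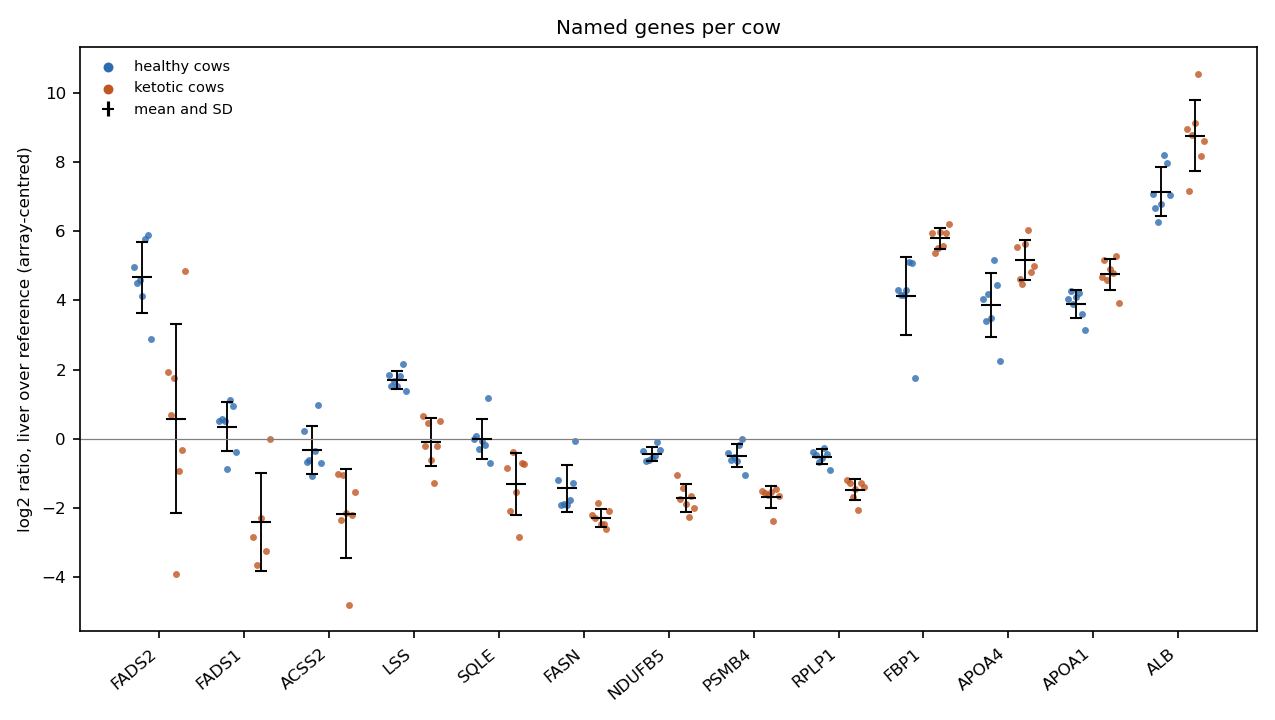
Log2 ratio of liver over reference, array-centred, for 13 named genes in each cow; points are cows, bars the mean and SD of the cows with values. FADS2 averaged 0.58 in ketotic and 4.68 in healthy cows, and LSS -0.10 and 1.70.

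Of 33 lists, 13 were lower and none higher in ketotic cows in the exact permutation test of per-cow medians. Besides the lists given with their p above, growth hormone and insulin genes had an adjusted exact permutation p of 0.0214, stress genes of the endoplasmic reticulum 0.0350 and oxidative stress genes 0.0231; with an estimated correlation the adjusted p was 0.700, 0.63 and 0.63. Without healthy cow 7 the adjusted exact permutation p was 0.0590 for growth hormone and 0.0549 for endoplasmic reticulum genes, while amino acid catabolism (0.0459) and cytokine genes (0.00577) passed. This test asks whether a list moved between cows, not whether it moved more than other genes. The camera-type test passed 11 lists with the preset correlation, 6 upward and 5 downward, and none with an estimated one. The others of the 13 lower lists did not pass it even with the preset correlation. Their adjusted p there was 0.211 for fatty acid synthesis, 0.0555 for cholesterol synthesis, 0.677 for ubiquitin conjugation and 0.439 for growth hormone genes. It was 0.122 for endoplasmic reticulum, 0.0766 for oxidative stress, 0.0854 for macrophage and 0.606 for bile duct genes. The 13 lower lists kept a negative median difference under the 6 scalings compared. The median over all genes was negative under each of them too, from -0.07 with arrays centred on the same probes to -0.58 as deposited. A kept sign alone therefore does not set these lists apart from other genes. With arrays centred on the same probes, the ubiquitin conjugation list had a median of -0.022.

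Among probes without a gene name, probe_11529 rose 6.02-fold (adjusted p = 0.00713) and probe_22061 rose 4.84-fold (adjusted p = 0.00200), the latter with a value at every spot. The probe probe_21375 fell 5.53-fold (adjusted p = 0.0130) and probe_22319 fell 4.16-fold (adjusted p = 0.00801).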

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

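The tests of the correlation between the deviations of a cow's 2 arrays, of matched random lists and of other splits of the cows were set out before their results were seen; the other tests of explanations below were chosen after. In each group of 7 cows, the named genes and 4 measures of array quality were searched for a cow far from the others. Of 158 such groups of values, 22 held one, where chance gives about 1 in 20, or 7.9; the values of a cow are not independent, and 15 of the 22 belonged to healthy cow 7.

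Healthy cow 7 had a median correlation of 0.408 with its group, against 0.870 to 0.887 for the others. Its log2 ratios lay below those of the other healthy cows for APOB (0.41, others from 7.99), MTTP (-0.28, others from 3.40), IGF1 (0.33, others from 2.84), FBP1 (1.74, others from 4.15), ACADVL (0.27, others from 2.26), GLUD1 (0.55, others from 2.03), PC (0.88, others from 2.24), DBI (-0.64, others from 0.36), AHSP (-0.50, others from 0.78) and MMP9 (-0.25, others from 0.55). They lay above for DCN (1.17, others up to -0.29), FASN (-0.072, others up to -1.19), SREBF1 (0.96, others up to 0.16) and GNLY (0.84, others up to 0.16).

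The labels of healthy cow 7 carry no description, which those of the other cows do, and its array with liver in Cy3 lists the channels in another order than the other such arrays. Exchanged dyes on the arrays of healthy cow 7 are argued against by its hepatocyte markers, whose median ratio was positive on both of its arrays, the lower at 2.70. Independent noise of single arrays is argued against by the correlation of 0.700 between the deviations of its 2 arrays from the other healthy cows. A smaller share of hepatocytes would raise the markers of other cells alike; hepatocyte markers lay 2.40 below the other healthy cows (a difference of -2.40) and stellate cell and fibroblast markers 2.48 above, but 3 lists (macrophage, lymphocyte and endothelial cell) lay below all other healthy cows by more than their SD. A liver sample rich in connective tissue, another reference RNA or a wrong label stay open, since the rise of the stellate markers is not excluded by these tests. No biological explanation was tested, because the labels give none for this cow.

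Among the other cows, ketotic cow 5 lay below its group for ACSS2 (-4.81, others from -2.36), PGAM1 (-3.48, others from -2.67) and PSMB4 (-2.38, others from -1.65). Ketotic cow 7 had PC at 2.43, others from 3.05, and KRT14 at 3.26, others up to 1.66. Healthy cow 6 had SQLE at 1.19, others up to 0.07, and healthy cow 2 had UBE2E1 at -0.18, others up to -0.59.

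Most genes that passed were lower in ketotic cows. Chance is argued against for the counts, though not for their direction, by 100 splits drawn from the 1716 possible. Of these 100 splits of the 14 cows, 1 gave as many genes, the real one with 929, and the highest other gave 1. For probes the real split gave 1050 and the highest other 1. Centring over different probes is argued against as the whole cause, since with all arrays centred on the same probes 74.9% of passing probes were lower (73.2% to 81.9% with a cow left out), although it accounts for part of the excess. More empty spots are argued against as the whole cause by the covariate fit, where 168 genes passed, 8 higher and 160 lower. The 865 genes that fell had a median difference of -0.79 (median SE 0.189) without it and -0.68 (SE 0.215) with it, 85.8% of the former. Many calls ended as the error grew and the difference shrank. These genes were picked by the fit without the covariate in the same cows, so that share can be too high. The share of empty spots correlated with the group at r = 0.550, so the fit separates them only in part. A wider spread of ratios is argued against as the whole cause, since 93.6% of passing genes were lower with arrays scaled to one spread. That share cannot show a partial effect: the genes that fell went from 865 to 515, and those that rose from 64 to 35. The labels give feed restriction for the ketosis group alone, so the design cannot tell its effect from that of ketosis. Any unequal labelling that these measures do not capture stays open.

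Genes of oxidative phosphorylation, the proteasome and cytosolic ribosomal proteins were lower together. A trend with the level of the ratio was tested with 10000 random lists matched on mean ratio and completeness. The share with a median as low was 0.0011 for ribosomal proteins and 1e-04, the smallest the draws can give, for the other 2 lists. Such draws hold unrelated genes, while list members correlated at an estimated 0.34 for ribosomal proteins, 0.26 for the proteasome and 0.31 for oxidative phosphorylation. The shares are therefore too small, and they do not decide whether such a trend was the whole cause. The matched lists themselves had medians of -0.43 against -0.60 for ribosomal proteins, -0.29 against -0.61 for the proteasome and -0.20 against -0.56 for oxidative phosphorylation, where the median over all genes was -0.18; level and completeness were matched together and not told apart. The wider spread of ratios is argued against as the whole cause by the same lists with arrays scaled to one spread. There the highest exact permutation p, not adjusted, was 0.0221, for ribosomal proteins at a difference of -0.33. The list medians went from -0.60 to -0.34 for ribosomal proteins, from -0.61 to -0.48 for the proteasome and from -0.56 to -0.54 for oxidative phosphorylation. A part of the ribosomal shift can thus come from the spread, and the median over all genes was -0.16 there. A smaller share of hepatocytes would raise the markers of other cells alike. The criterion set last asked for at least 1 marker list of another cell type to be lower under both scalings, with or without healthy cow 7. Earlier criteria, on hepatocyte markers alone and then on all cows, had left the question open. Without healthy cow 7, the macrophage list, 1 of 7, was lower under both scalings (-0.72 with centred arrays, -0.83 with one spread, adjusted exact permutation p = 0.00204 and 0.00408). With all cows 0 of 8 lists were lower under both scalings at an adjusted p below 0.05: macrophage markers had 0.0606 and 0.00466, and bile duct markers 0.0466 and 0.221, while the difference was negative under both scalings for 5 of the 8. The result rests on 1 list, on a criterion changed after values were seen and on leaving out the cow that stands apart. A smaller share of hepatocytes, alone or together with a loss of macrophages, therefore stays open. The hepatocyte markers themselves had a median difference of 0.53 with centred arrays and of -0.67 with one spread. Chance was not excluded for the count of lists in the camera-type test: 54 of 100 splits gave as many as the real 11, with a highest of 22, so that count may reflect genes moving together within cows.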

How the results depend on the processing

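The covariate, print-block, all-spot, zero and ceiling settings, the permutation of list medians, and the estimated correlation without healthy cow 7 were chosen after seeing the data; the others were planned. Against 1050 probes and 929 genes, values as deposited gave 2859 and 2477, one spread 576 and 550, quantile normalisation 581 and 562, the liver in Cy5 alone 20 and 12, array weights 1775 and 1409, a threshold of 0.01 227 and 227, and the covariate 146 and 168. Asking for values in 2 cows per group and taking 1 array as enough gave 684 probes. Leaving out each cow in turn gave 643 probes (without healthy cow 6) to 1649 (without healthy cow 7), 652 to 1368 genes and 10 to 14 lists; without healthy cow 7 the lists passing upward went from 6 to 2. Passing genes were mostly lower under each of these settings. Against 11 lists, the estimated correlation gave 0 with or without healthy cow 7 (2 and 0 at an unadjusted p below 0.05). Leaving out the 25% of probes with the largest dye difference gave 5 lists, all downward. The median difference over all genes was -0.18, against -0.58 as deposited and -0.07 with arrays centred on the same probes. With one spread, the difference reversed to -0.074 for ALB and -0.027 for APOA1, and the mean z less that of all genes to -0.52 for lipoprotein, -0.90 for acute phase, -0.70 for complement and -0.75 for hepatocyte genes; FRZB went to -0.18 with ceiling values kept. Over 75 named genes, 2054 of 2301 values under alternatives kept their side of the threshold, 198 lost a call and 46 gained one. Another 3 changed direction with a call in at least 1 of the 2 fits. Changes of direction without a call in either fit stand among the 2054. Examples without healthy cow 7 were ACADVL (0.077 to -0.26) and PPARA (0.22 to -0.13). The lost calls were unevenly spread: 45 were lost with the liver in Cy5 alone and 27 with the share of empty spots as a covariate. The marker contrast was 1.86 with urea cycle genes, and the dye-swap correlation 0.618 by Spearman. The cause was not tested for any of these. No paired analysis was possible because the replicate numbers only count the cows within a group and no label pairs a ketotic with a healthy cow. The arrays' signal over background was not analysed here, so dim probes cannot be told from bright ones except by their empty spots.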

Other observations

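The gene families in this part were chosen after seeing the data. Some of these families held many genes that were lower in ketotic cows, though most members of most families did not pass. Of 15 vacuolar ATPase subunits, which acidify lysosomes, 8 fell (9 without healthy cow 7), with a median difference of -0.60. Of 63 mitochondrial ribosomal proteins 16 fell (26 without healthy cow 7), with a median of -0.40. Of 13 chaperonin and prefoldin subunits, which fold new proteins, 6 fell (7 without that cow). Of 44 translation factors 11 fell and 1 rose, of 21 aminoacyl-tRNA synthetases 5 fell, of 38 spliceosome proteins 10 fell and 1 rose, and of 15 mitochondrial import genes 3 fell. Of 63 zinc finger genes 1 fell and 1 rose, of 135 solute carriers 7 fell and 2 rose, and of 7 keratins 1 fell. Without healthy cow 7, 17 translation factors, 6 synthetases, 13 spliceosome, 6 mitochondrial import, 2 zinc finger and 10 solute carrier genes fell. No family passed with an estimated correlation (lowest adjusted p = 0.178).

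Probes with over 10 empty spots of 56 had a median difference of 0.49, with 17 passing higher and 3 lower. Probes with no empty spot had one of -0.14, with 63 higher and 634 lower. Values in all 7 healthy cows and at most 2 ketotic cows were found for 34 probes, which were not tested, and the reverse for 3 probes. Among the 34 were probes of TMEM45A and PYM1 with values in 0 ketotic cows, named here after their values were seen. A cow's value needed both arrays, and spots without a usable ratio made up 16.5% in ketotic against 11.9% in healthy cows. Whether that accounts for the 34 against 3 probes was not tested, so a missing value does not show that a gene was silent.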
